A study of Drosophila melanogaster with 4 samples.

How the data were processed

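Libraries were made from RNA extracted with Trizol from wing imaginal discs of larvae at the third instar and sequenced on an Illumina HiSeq platform, per the labels. There were 2 groups, y w control and Paip1 mutant, with 2 libraries each. The labels number the replicates but do not say that they came from separate collections of larvae, so p-values measure only the spread between these libraries, which may be technical.

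One table of the whole series was used, with 17559 genes. It holds 1 value per gene and library, which the authors deposited with no unit in the header. The values were read as TPM because they are not whole and sum to between 91.95% and 99.65% of the nominal TPM total per library. The mean columns of each group are the authors' deposited means of these TPM values. The authors' comparison columns hold a fold change (ratio of mutant to control), its log2 value, a p-value and an adjusted p-value, per the file headers. FastQC, TopHat, RSEM, DESeq and the genome build dm6 are listed in the submitters' processing notes, without versions or roles. How reads were assigned to genes or copies, whether strand was used, and which filters were applied are not given in the sources used here. The listed values sum to less in the mutant libraries (91.95% and 93.6% of that total) than in the control libraries (99.57% and 99.65%). The remainder was not analysed here. TPM divides by transcript length and by the library's own total, so a gene that takes a large share of a library lowers all others, and neither reads nor depth can be recovered. No interval from counting error was therefore given, and the precision rests on 2 libraries per group.

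Gene IDs were matched to current symbols and dm6 coordinates in Ensembl annotation 115, where 17252 matched and 307 did not. Transposable element coordinates came from the same annotation. All numeric columns were assigned to a library, a group mean or the authors' comparison. The libraries of a group were compared first, and none held the same values as another.

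Levels are means ± SD of TPM over 2 libraries. The test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with moderated variances that follow the mean. It was two-sided and covered 8605 genes at 1 TPM or more in at least 2 libraries, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The pseudocount of 1 makes the log2 fold changes of low genes smaller than their true ratio. The design foresaw a count model if the table held counts and this model if it held normalized values. The residual degrees of freedom were 2 and the prior degrees of freedom 3.27. Shares and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

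The comparison, its test, 40 gene lists and the rule for named genes were fixed before the data were examined. The lists cover immune, stress, growth, translation, metabolic and developmental genes, markers of other cell types and replication-dependent histones. For each list the members past the threshold were counted over all genes tested and again adjusted over the list alone. The second count is given where it differed. The 39 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other tested genes. Their p-values had Benjamini-Hochberg adjustment over the lists. Of these, 10 passed. None of the 10 calls held with an estimated correlation. That setting rests on the 2 residual degrees of freedom and has little power here, so losing a call with it does not decide on a list. The fry test, which asks whether a list's genes move one way on balance without comparing them with other genes, passed 8 lists. These were 6 of the 10 and the neuron and glia (adjusted p = 0.029) and sex-biased (0.029) lists. It did not pass the wing identity (adjusted p = 0.0612), cell cycle (0.137), Wnt, Hh and Dpp (0.171) and hemocyte (0.314) lists. The median, mean and camera direction of a list differed in sign for melanization, unfolded protein response, apoptosis, mitochondrial ribosomal protein, insulin and TOR, autophagy, cuticle, EGFR, trachea, neuron and glia, and salivary gland lists. None of these passed camera.

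The rule named Paip1, y and w. In each direction it then named the 12 genes with the largest absolute log2 fold change among those past the threshold, with both mutant libraries beyond both control libraries and a mean of at least 1 TPM. Numbered genes were passed over, and the 2 largest of them per direction were named too. It added up to 4 members of each list past the threshold, by smallest p, or the 2 with the highest mean where none passed, and the 2 with the highest mean of each list of another cell type. This gave 175 genes, from which the text takes those that best describe each group. Of the 161 past the threshold besides Paip1, 98 kept the call without any 1 library. Genes that did not are marked with the value without that library where they are named. A few genes outside the rule are named with the remark that they were chosen after their values were seen. upd2 and several genes of the closing observations also lie outside the rule and carry no such remark.

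The test was checked on simulated data for the comparison of Paip1 mutant with control, with 8605 genes and 200 changed genes per fold. At 2-fold, 86.3% of changed genes were called with 4 unchanged genes, and at 4-fold 97.9% with 9 unchanged genes. At 1.5-fold 0% were called, and 0 calls had the wrong direction. The simulated changes were few and balanced up and down, whereas 3852 genes passed in the data, more of them lower. The adjusted threshold depends on the number of changed genes, so these rates do not carry over to the data. The alternatives were leaving out each library, the replicate number as a block, pseudocounts of 0.1 and 0.5, no filter on low values and a mean of at least 5 TPM. Further ones were median-ratio scaling, rescaling to a common sum, robust variance estimates without a trend, and leaving out genes with transposon sequence in exons. Where a library was left out, the lone library of its group was assumed to vary like the other group.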

Results

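RNA from wing imaginal discs of Drosophila melanogaster larvae at the third instar was sequenced in 4 libraries, 2 from y w control larvae and 2 from Paip1 mutant larvae. Wing discs are the larval epithelial sacs that form the adult wing and dorsal thorax. Paip1 encodes a protein that binds poly(A)-binding protein, the factor that coats the poly(A) tail of mRNA during translation. The deposited table held 17559 genes with 1 value per gene and library, read as TPM, the length-corrected share of transcripts. The listed values summed to 995750 and 996531 TPM in control replicates 1 and 2, and to 919460 and 936038 TPM in mutant replicates 1 and 2. At least 1 TPM was reached by 8187 and 8082 genes in the control libraries and by 8494 and 8476 genes in the mutant libraries. Across the tested genes, which are not independent replicates, log2(TPM + 1) correlated at Pearson r = 0.984 between the control libraries, 0.978 between the mutant libraries and 0.862 to 0.886 between groups. The read depth is unknown, because TPM keeps no depth.

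The comparison asked which transcripts differ between Paip1 mutant and control discs. The labels give neither the Paip1 allele nor whether mutant and control share a genetic background. Effects of the strain can therefore not be told apart from effects of the Paip1 mutation in any change below. In the mutant discs the Paip1 transcript fell from 117 ± 6.27 to 2.30 ± 0.106 TPM (SD, n = 2 in each group here and throughout). Of 20 wound response genes 17 rose, among them the hormone Ilp8, the cytokines upd1 and upd3 and the matrix protease Mmp1, each more than 8-fold (camera adjusted p = 3.33e-10, and adjusted p = 0.608 with an estimated correlation). Of 27 wing identity and proximodistal genes 20 fell (camera adjusted p = 0.000716, and adjusted p = 0.962 with an estimated correlation). Among them were the notum genes eyg and tup and the wing selector gene vg, and pnr, also a notum gene, fell too. Of 13 damage response genes 12 rose (camera adjusted p = 7.21e-09, and adjusted p = 0.608 with an estimated correlation) and of 22 muscle markers 20 rose (camera adjusted p = 4.91e-11, and adjusted p = 0.75 with an estimated correlation), while the ecdysone-inducible genes ImpE2 and ImpE3 fell.

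Paip1 (FBgn0034181, listed as CG8963) is a protein-coding gene on the minus strand of chromosome 2R, from 17016226 to 17019522 in dm6. It was at 112 and 121 TPM in control replicates 1 and 2 and at 2.37 and 2.22 TPM in mutant replicates 1 and 2 (log2 fold change -5.16, SE 0.12, adjusted p = 3.54e-05). In the authors' deposited table its log2 fold change was -5.52, with an adjusted p of 2.72e-262. The control strain is named for mutations in y, a pigmentation gene, and w, an eye colour gene. The y transcript went from 5.73 ± 3.4 to 0.665 ± 0.403 TPM (log2 fold change -1.94, adjusted p = 0.0178), and its call was lost without control replicate 1 (adjusted p = 0.0751), without mutant replicate 1 (adjusted p = 0.0889) and without mutant replicate 2 (adjusted p = 0.11). The w transcript went from 0.02 ± 0.0283 to 2.04 ± 0.339 TPM (log2 fold change 1.57, adjusted p = 0.0092), with adjusted p = 0.0509 without control replicate 1.

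Of 8605 genes tested with limma, 3852 changed at a Benjamini-Hochberg adjusted p under 0.05, 1346 higher and 2506 lower in the mutant. At an unadjusted p under 0.05, 4753 genes passed. The 1440 genes that changed at least 2-fold comprised 837 higher and 603 lower. The median log2 fold change of all tested genes was -0.22. With TPM rescaled by median ratios, where that median was -0.003, 3333 genes changed, 1864 higher (55.9%, against 34.9%) and 1469 lower. With the listed values rescaled to a common sum, 3407 genes changed, 1509 higher (44.3%) and 1898 lower. With no filter on low values 3231 changed, 1531 higher (47.4%) and 1700 lower. No gene called in the main test changed sign in any setting tried. Leaving out control replicate 1 brought the number of changed genes to 1013 (607 higher, 406 lower), control replicate 2 to 1099 (634 higher, 465 lower) and mutant replicate 1 to 1838 (874 higher, 964 lower). For lists of genes, counts with each library left out in turn stand in the order control replicates 1 and 2, then mutant replicates 1 and 2.

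**Figure D1:**
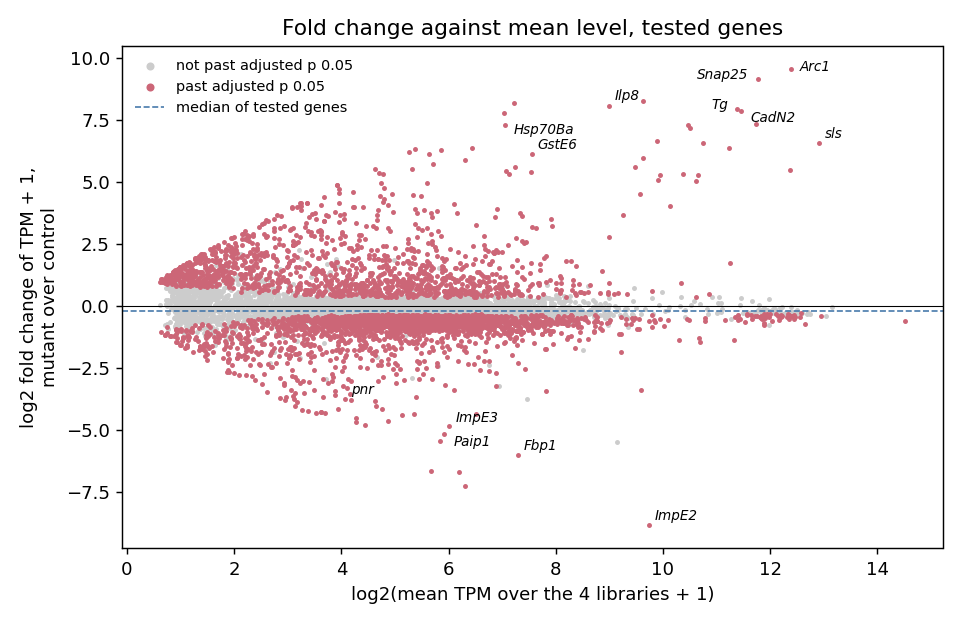
Log2 fold change of TPM + 1, mutant over control, against log2 of the mean TPM over the 4 libraries plus 1 for the 8605 tested genes, with 1 point per gene. Red points are the 3852 genes past adjusted p 0.05, grey points the rest, and the dashed line is the median of the tested genes at -0.22; labelled genes include Paip1 at -5.16 and Ilp8 at 8.09.

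Among wound response genes, Ilp8, a relaxin-like hormone released by damaged discs, rose from 3.29 ± 3.05 to 1012 ± 139.5 TPM (log2 fold change 8.09, SE 0.51, adjusted p = 0.000609). Ilp8 also belongs to a set of 24 genes at 1000 TPM or more in the mutant, described at the end. Mmp1, a matrix metalloproteinase, rose from 39.1 ± 6.55 to 354 ± 11.8 TPM (log2 fold change 3.16, SE 0.15, adjusted p = 0.000265). The interleukin-6-like ligands of the JAK-STAT pathway rose as well, upd1 from 6.45 ± 0.127 to 129.5 ± 23.2 TPM (log2 fold change 4.12, SE 0.15, adjusted p = 0.000127). upd3 rose from 1.7 ± 1.33 to 57.6 ± 9.26 TPM (log2 fold change 4.52, SE 0.36, adjusted p = 0.00112). Of 20 tested JNK targets and wound response genes, 17 rose and 0 fell (camera adjusted p = 3.33e-10, and adjusted p = 0.608 with an estimated correlation). chinmo, a transcription factor of juvenile cells that is among them, rose from 3.8 ± 0.863 to 25.9 ± 2.91 TPM (log2 fold change 2.49, adjusted p = 0.000859). Of 11 tested Turandot and JAK-STAT genes, 7 rose and 2, hop and Stat92E (the kinase and the transcription factor of the pathway, named after their values were seen), fell (camera adjusted p = 0.000502, and adjusted p = 0.75 with an estimated correlation). The call of hop was lost without control replicate 1 or 2 (adjusted p = 0.151 and 0.156), without mutant replicate 1 (0.0733) and under median-ratio scaling (0.0703). That of Stat92E was lost without control replicate 1 or 2 (adjusted p = 0.122 and 0.137) and without mutant replicate 1 (0.0517). Socs36E, a feedback inhibitor of this pathway, rose from 44.9 ± 1.97 to 208 ± 11.7 TPM (log2 fold change 2.18, adjusted p = 0.000308). Tep4, a thioester protein, rose from 40.1 ± 6.29 to 186 ± 13.1 TPM (log2 fold change 2.19, adjusted p = 0.00071). The 3 unpaired ligands upd1, upd2 and upd3 stand in both lists. Under median-ratio scaling the counts were 17 higher and 0 lower for the wound list and 8 higher and 1 lower for the JAK-STAT list. Without control replicate 1 they were 12 and 0 for the wound list and 7 and 0 for the JAK-STAT list.

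**Figure D2:**
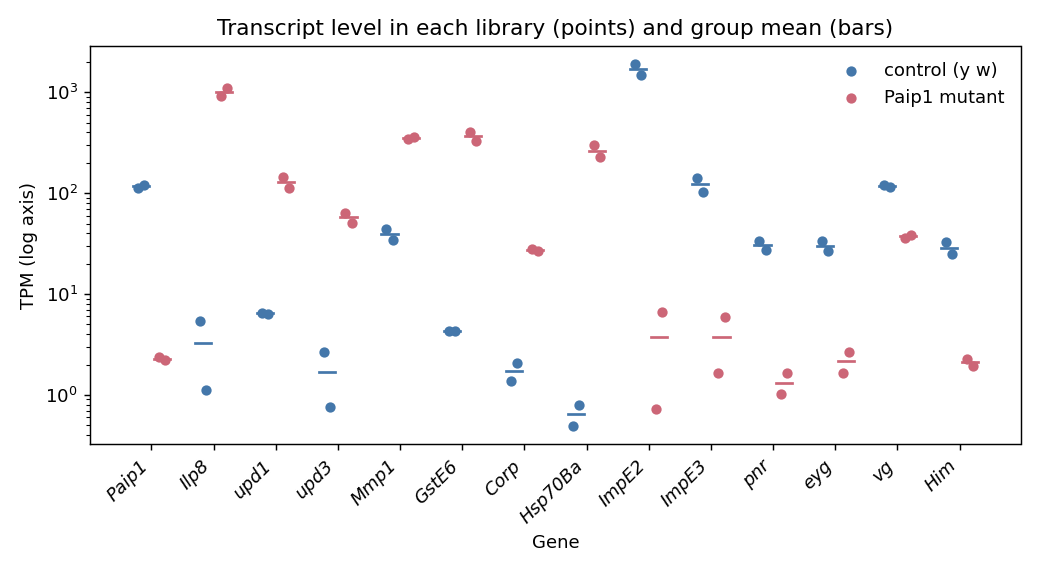
TPM of 14 genes in each library on a log axis, with 1 point per library and a bar at each group mean (blue, 2 control libraries; red, 2 Paip1 mutant libraries). Ilp8 lies at 913 TPM or more in both mutant libraries and at 5.44 TPM or less in both control libraries, and pnr at 1.63 TPM or less in the mutant and 27.1 TPM or more in control.

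In the DNA damage and stress programme driven by Xrp1 and p53, Corp, a p53 target, rose from 1.73 ± 0.488 to 27.2 ± 0.778 TPM (log2 fold change 3.38, SE 0.17, adjusted p = 0.000313). The double-strand break repair genes Ku80 and mre11 rose from 15.9 ± 1.9 to 64 ± 0.75 TPM (log2 fold change 1.95, SE 0.13, adjusted p = 0.000657) and from 37.4 ± 2.73 to 139.8 ± 7.35 TPM (log2 fold change 1.88, SE 0.12, adjusted p = 0.000554). Of 13 tested members, 12 rose and 1, the ribonucleotide reductase subunit RnrS (named after its value was seen), fell (camera adjusted p = 7.21e-09, and adjusted p = 0.608 with an estimated correlation). Under median-ratio scaling 12 rose and 0 fell. The fall of RnrS did not pass without control replicate 1 or 2 (adjusted p = 0.0563 and 0.172), nor without mutant replicate 1 or 2 (0.163 and 0.0942). Among 13 tested genes of the apoptosis machinery 5 rose and 3 fell (camera adjusted p = 0.444). The counts were 2 and 1, 2 and 1, 4 and 2, and 4 and 4 with each library left out in turn. The cell death inducer hid rose from 36.4 ± 4.82 to 80.8 ± 1.52 TPM (log2 fold change 1.13, adjusted p = 0.00344). The TNF ligand egr rose from 6.63 ± 0.446 to 14.6 ± 0.615 TPM (log2 fold change 1.03, adjusted p = 0.00439). The TNF receptor wgn fell from 37.9 ± 0.545 to 10 ± 0.912 TPM (log2 fold change -1.83, adjusted p = 0.000693). The genes hid, egr and rpr of the apoptosis list and upd3 of the wound list stand in the damage list too. So do GstE6 of the oxidative stress list and RnrL and RnrS of the cell cycle list. RnrL (named after its value was seen) is 1 of the 12 that rose, and its call did not hold without any single library, as given with the cell cycle genes.

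Detoxification genes moved in both directions. The glutathione S-transferase genes GstE6 and GstD5 rose from 4.3 ± 0.0566 to 369 ± 51.4 TPM (log2 fold change 6.12, SE 0.14, adjusted p = 3.54e-05) and from 0.24 ± 0.339 to 50.1 ± 10.5 TPM (log2 fold change 5.38, SE 0.26, adjusted p = 0.000288). Gclc, which makes the first step of glutathione synthesis, rose from 10.1 ± 2.01 to 44 ± 5.29 TPM (log2 fold change 2.03, adjusted p = 0.00146). Of 38 tested oxidative stress and glutathione S-transferase genes 18 rose and 9 fell (camera adjusted p = 0.00385, and adjusted p = 0.75 with an estimated correlation). That call was lost under median-ratio scaling (adjusted p = 0.0537) and with no filter on low values (adjusted p = 0.127), and 10 rose and 3 fell without control replicate 1, 10 and 4 without control replicate 2 and 12 and 5 without mutant replicate 1. Neighbouring glutathione S-transferase genes are close copies, which leaves the division of reads among them uncertain. Of 26 tested cytochrome P450 genes 8 rose and 7 fell (camera adjusted p = 0.106, and 0.0116 without mutant replicate 2). These numbers became 5 and 3, 4 and 6, 4 and 3, and 9 and 4 with each library left out in turn, against 9 higher and 7 lower adjusted over the list alone. Under median-ratio scaling 9 were higher and 4 lower. Cyp9f2 rose from 3.42 ± 0.248 to 19.4 ± 1.51 TPM (log2 fold change 2.21, adjusted p = 0.000609). Cyp4e2 fell from 23.2 ± 5.27 to 1.75 ± 0.113 TPM (log2 fold change -3.12, adjusted p = 0.000568).

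Among 23 tested genes of the unfolded protein response and ATF4, 6 rose and 7 fell (camera adjusted p = 0.579). They numbered 3 and 0, 3 and 1, 3 and 2, and 4 and 8 with each library left out in turn, against 7 and 4 under median-ratio scaling. Gadd45, a stress-inducible activator of MAP kinase signalling, rose from 36.4 ± 10.2 to 339 ± 27.2 TPM (log2 fold change 3.21, SE 0.21, adjusted p = 0.000639). trbl, a pseudokinase, rose from 50.4 ± 0.545 to 164 ± 0.686 TPM (log2 fold change 1.68, SE 0.10, adjusted p = 0.000509). Thor, the 4E-BP that restrains cap-dependent translation, rose from 29.8 ± 4.41 to 127 ± 36 TPM (log2 fold change 2.04, SE 0.23, adjusted p = 0.00299). Of 25 tested heat shock genes and cochaperones 4 rose and 4 fell (camera adjusted p = 0.178, with 0.000871 without control replicate 1 and 0.923 without control replicate 2). Those counts were 8 and 0, 2 and 3, 1 and 0, and 3 and 3 with each library left out in turn. Hsp70Ba rose from 0.64 ± 0.212 to 263 ± 49.9 TPM (log2 fold change 7.32, SE 0.18, adjusted p = 4.14e-05), but it shares nearly all its sequence with 5 other Hsp70 genes, so its level is uncertain. The 6 copies together summed to 6844 ± 4263 TPM in control and 8209 ± 1054 TPM in the mutant, a difference smaller than the spread between the control libraries.

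Among genes that pattern the wing disc, pnr, a GATA factor of the notum, fell from 30.4 ± 4.67 to 1.33 ± 0.431 TPM (log2 fold change -3.76, SE 0.20, adjusted p = 0.000359). eyg, a notum Pax gene, fell from 30.2 ± 4.84 to 2.17 ± 0.721 TPM (log2 fold change -3.31, SE 0.21, adjusted p = 0.000657). tup, a LIM homeodomain gene of the notum, fell from 18.2 ± 1.52 to 2.22 ± 0 TPM (log2 fold change -2.57, SE 0.14, adjusted p = 0.000416). sc, a proneural gene, fell from 42 ± 3.66 to 7.38 ± 1.39 TPM (log2 fold change -2.37, SE 0.16, adjusted p = 0.000734). vg, the wing selector gene, fell from 119 ± 4.62 to 37.3 ± 2.17 TPM (log2 fold change -1.64, SE 0.11, adjusted p = 0.00071). Of 27 tested wing identity and proximodistal genes 20 fell and 2, Ubx and Lim1 (named after their values were seen), rose (camera adjusted p = 0.000716, and adjusted p = 0.962 with an estimated correlation). Under median-ratio scaling 19 fell and 4 rose, and without control replicates 1 and 2 the numbers lower were 11 and 10. The rise of Ubx did not pass without control replicate 1 or 2 (adjusted p = 0.0875 and 0.158), nor without mutant replicate 1 or 2 (0.0652 and 0.0963). Of 14 tested adult muscle precursor markers, genes of the myoblasts that lie on the notum epithelium, 8 fell and 2 rose (camera adjusted p = 0.399). The counts were 1 and 1, 3 and 1, 2 and 1, and 9 and 1 with each library left out in turn. Him, which holds those myoblasts undifferentiated, fell from 28.7 ± 5.42 to 2.11 ± 0.219 TPM (log2 fold change -3.25, adjusted p = 0.000398).

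Of 44 tested Wnt, Hh and Dpp patterning genes 26 fell and 4 rose (camera adjusted p = 0.0393, and adjusted p = 0.962 with an estimated correlation). arr, a Wingless co-receptor, fell from 93.9 ± 4.47 to 25.4 ± 5.19 TPM (log2 fold change -1.86, adjusted p = 0.00157). kn, a Hedgehog-dependent factor, fell from 16.3 ± 1.85 to 3.22 ± 1.15 TPM (log2 fold change -2.06, adjusted p = 0.00296). Doc1, a T-box gene, fell from 39.5 ± 5.19 to 17.2 ± 1.69 TPM (log2 fold change -1.15, adjusted p = 0.00447). The 4 that rose were dlp and, named after their values were seen, dally, Wnt10 and sog. Without control replicate 1 or 2 none of the 4 calls held, with adjusted p = 0.0524 and 0.0779 for dlp, 0.112 and 0.135 for dally, 0.0828 and 0.0714 for Wnt10, and 0.0525 and 0.0501 for sog. Adjusted over the list alone 30 fell and 4 rose, and under median-ratio scaling 19 fell and 7 rose. Without control replicates 1 and 2 and mutant replicate 1 the numbers lower were 5, 6 and 14, with an adjusted p of 0.067 without control replicate 1. The list's adjusted p was 0.0691 over genes with a mean of at least 5 TPM and 0.0781 without genes with transposon sequence in exons. Of 25 tested Notch pathway and E(spl) genes 13 fell and 5 rose (camera adjusted p = 0.402). These numbers became 3 and 1, 3 and 1, 7 and 1, and 10 and 2 with each library left out in turn, against 14 and 5 adjusted over the list alone and 8 and 6 under median-ratio scaling. The Notch targets E(spl)m6-BFM and E(spl)m2-BFM fell from 14.1 ± 0.361 to 2.39 ± 0.431 TPM (log2 fold change -2.16, adjusted p = 0.000945) and from 120.4 ± 14 to 34.6 ± 5.16 TPM (log2 fold change -1.77, adjusted p = 0.00153). EGFR signalling had 10 of 21 tested genes lower and 6 higher (camera adjusted p = 0.792). They numbered 1 and 1, 2 and 1, 4 and 2, and 8 and 2 with each library left out in turn, against 6 lower and 8 higher under median-ratio scaling. The Hippo pathway and its targets had 9 of 23 lower and 4 higher (camera adjusted p = 0.638). Those counts were 1 and 0, 1 and 0, 3 and 2, and 9 and 3 with each library left out in turn, against 5 and 4 under median-ratio scaling. dachs, an atypical myosin of that pathway, fell from 184 ± 4.27 to 88.7 ± 10.8 TPM (log2 fold change -1.05, adjusted p = 0.00385).

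**Figure D3:**
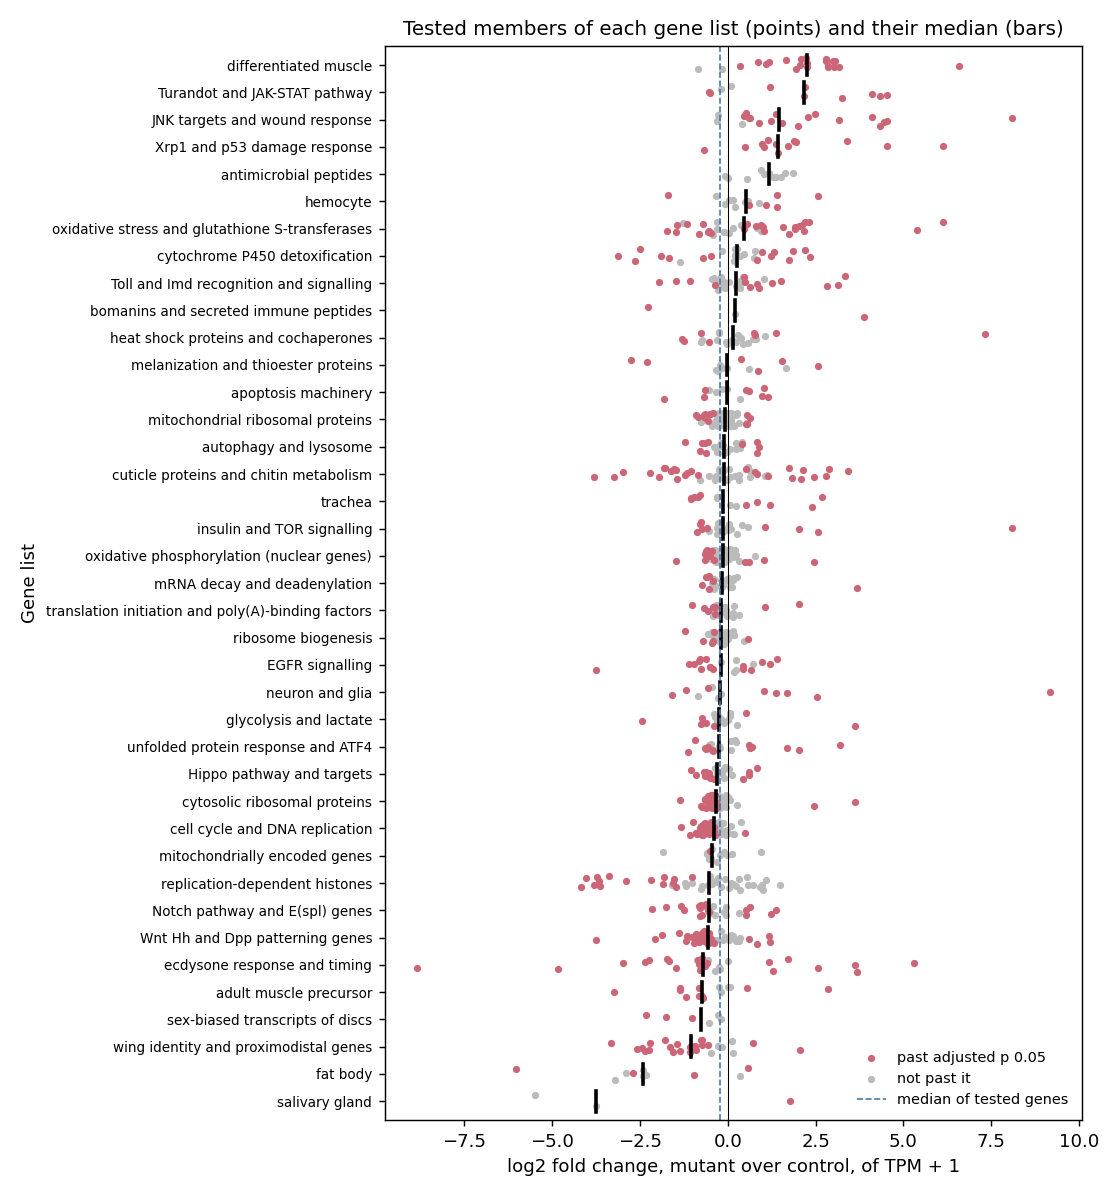
Log2 fold change of TPM + 1, mutant over control, of each tested member of the 39 lists with at least 3 tested members, with 1 point per gene, red past adjusted p 0.05 and grey otherwise. Black bars are list medians, which run from -3.75 for salivary gland markers to 2.24 for differentiated muscle markers, and the dashed line is the median of all tested genes at -0.22.

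Cell cycle genes were among those that fell. Cdk1, the mitotic kinase, fell from 194 ± 3.17 to 92 ± 7.52 TPM (log2 fold change -1.07, SE 0.11, adjusted p = 0.00254). dap, an inhibitor of Cyclin E, fell from 61.5 ± 5.11 to 23.7 ± 1.04 TPM (log2 fold change -1.34, SE 0.12, adjusted p = 0.00159). Of 62 tested cell cycle and DNA replication genes 33 fell and 1, the ribonucleotide reductase subunit RnrL (named after its value was seen), rose (camera adjusted p = 0.00162, and adjusted p = 0.962 with an estimated correlation). Under median-ratio scaling 20 fell and 3 rose. The rise of RnrL did not pass without control replicate 1 or 2 (adjusted p = 0.221 and 0.107), nor without mutant replicate 1 or 2 (0.0789 and 0.117). Without control replicates 1 and 2 and mutant replicate 1 the numbers lower were 3, 2 and 9. Of 44 tested replication-dependent histone genes 15 fell and 0 rose (camera adjusted p = 0.264, with 0.0125 under median-ratio scaling, where 14 fell, and 0.0254 over genes with a mean of at least 5 TPM, where 8 fell). These histone genes are near-identical copies whose reads cannot be placed with certainty, and their mRNAs lack a poly(A) tail.

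Many ribosomal protein transcripts fell by small amounts in TPM as deposited. Of 86 tested cytosolic ribosomal protein genes 46 fell and 2 rose, 55 and 2 adjusted over the list alone (camera adjusted p = 9.61e-05, and adjusted p = 0.962 with an estimated correlation). The list's median log2 fold change was -0.34, which is -0.12 from that of all tested genes. Under median-ratio scaling 4 fell and 2 rose and the call was lost (adjusted p = 0.0717). Without control replicates 1 and 2 and mutant replicates 1 and 2 the numbers lower were 2, 3, 7 and 9. RpL38 fell from 3701 ± 84.6 to 1443 ± 10.3 TPM (log2 fold change -1.36, SE 0.09, adjusted p = 0.000753). RpS28b fell from 4739 ± 176 to 2790 ± 67.8 TPM (log2 fold change -0.76, adjusted p = 0.00437). The 2 that rose were RpS5b, a paralogue of RpS5a, which rose from 1.31 ± 0.0778 to 11.8 ± 2.14 TPM (log2 fold change 2.46, adjusted p = 0.001), and RpL37-2, which was listed at 0 in both control libraries and at 6.7 and 18.7 TPM in mutant replicates 1 and 2. Of 39 tested translation initiation and poly(A)-binding factors 2 rose and 6 fell (camera adjusted p = 0.671). The counts were 1 and 0, 2 and 0, 2 and 1, and 2 and 6 with each library left out in turn, against 2 and 2 adjusted over the list alone and 7 and 2 under median-ratio scaling. Of 33 ribosome biogenesis genes 1 rose and 5 fell (camera adjusted p = 0.708). These numbers became 0 and 0, 0 and 0, 0 and 0, and 1 and 6 with each library left out in turn, against 0 and 0 adjusted over the list alone and 5 and 2 under median-ratio scaling. Of 75 mitochondrial ribosomal protein genes 4 rose and 10 fell (camera adjusted p = 0.814). They numbered 0 and 1, 0 and 0, 2 and 4, and 2 and 7 with each library left out in turn, against 2 and 3 adjusted over the list alone and 11 and 3 under median-ratio scaling. In mRNA decay and deadenylation 1 of 25 rose and 6 fell (camera adjusted p = 0.792). Those counts were 1 and 0, 1 and 0, 1 and 0, and 1 and 11 with each library left out in turn, against 5 and 3 under median-ratio scaling. twin, the CCR4 deadenylase, was the 1 that rose, from 85.4 ± 0.141 to 1133 ± 282 TPM (log2 fold change 3.69, SE 0.19, adjusted p = 0.000308). It belongs to a set of 24 genes at 1000 TPM or more in the mutant, described at the end, whose rise has no settled source.

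Genes of the metabolic lists moved both ways. ImpL2, a secreted antagonist of insulin-like peptides, rose from 49.3 ± 9.43 to 295 ± 35.3 TPM (log2 fold change 2.57, SE 0.17, adjusted p = 0.00071). Glut1, a glucose transporter, fell from 26.8 ± 4.55 to 4.21 ± 1.7 TPM (log2 fold change -2.45, SE 0.26, adjusted p = 0.00269). REPTOR, a transcription factor restrained by TORC1, rose from 13.5 ± 0.297 to 29.1 ± 2.28 TPM (log2 fold change 1.05, adjusted p = 0.00324). Atg4a, an autophagy protease, fell from 33.3 ± 2.28 to 13.6 ± 0.587 TPM (log2 fold change -1.23, adjusted p = 0.00199). Insulin and TOR signalling had 4 of 23 higher and 5 lower (camera adjusted p = 0.546). The counts were 4 and 0, 4 and 2, 5 and 1, and 4 and 2 with each library left out in turn, against 6 and 3 under median-ratio scaling. Glycolysis and lactate had 2 of 19 higher and 5 lower (camera adjusted p = 0.708). These numbers became 1 and 1, 1 and 1, 0 and 3, and 0 and 4 with each library left out in turn, against 2 and 3 adjusted over the list alone and 3 and 3 under median-ratio scaling. Autophagy and lysosome had 4 of 27 higher and 6 lower (camera adjusted p = 0.618). They numbered 0 and 1, 0 and 1, 5 and 3, and 3 and 7 with each library left out in turn, against 11 and 6 under median-ratio scaling. Nuclear genes of oxidative phosphorylation had 4 of 72 higher and 13 lower (camera adjusted p = 0.786). Those counts were 1 and 0, 1 and 0, 2 and 3, and 1 and 9 with each library left out in turn, against 4 and 11 adjusted over the list alone and 13 and 5 under median-ratio scaling. Mitochondrially encoded genes had 0 of 13 higher and 1, mt:ND3, lower (camera adjusted p = 0.774). The counts were 0 and 0, 0 and 0, 0 and 0, and 0 and 1 with each library left out in turn, against 0 and 0 adjusted over the list alone and 1 and 0 under median-ratio scaling. mt:ND3 was at 394 ± 48.5 TPM in control and 278 ± 6.72 TPM in the mutant (log2 fold change -0.50, adjusted p = 0.0277), and its call was lost without control replicate 1 (adjusted p = 0.191), without control replicate 2 (adjusted p = 0.0849), without mutant replicate 1 (adjusted p = 0.1) and without mutant replicate 2 (adjusted p = 0.0967).

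Ecdysone-inducible genes included some of the largest falls. ImpE2, a gene first found as inducible by ecdysone in imaginal discs, fell from 1705 ± 289 to 3.71 ± 4.23 TPM (log2 fold change -8.86, SE 0.68, adjusted p = 0.00106). ImpE3, found the same way, fell from 122 ± 28.5 to 3.76 ± 3 TPM (log2 fold change -4.83, SE 0.46, adjusted p = 0.00198). Cyp18a1, an enzyme that inactivates ecdysone, rose from 1.17 ± 0.0424 to 28.3 ± 13.1 TPM (log2 fold change 3.68, SE 0.32, adjusted p = 0.00152). Eip63E, a cyclin-dependent kinase gene, rose from 74.6 ± 5.08 to 3154 ± 1555 TPM (log2 fold change 5.29, SE 0.34, adjusted p = 0.000641). Eip63E too is in the set of 24 genes at 1000 TPM or more in the mutant whose rise has no settled source. Of 29 tested ecdysone response and timing genes 14 fell and 7 rose (camera adjusted p = 0.548). These numbers became 5 and 7, 8 and 5, 5 and 5, and 13 and 5 with each library left out in turn, against 17 and 7 adjusted over the list alone. Of 50 tested cuticle and chitin genes 15 fell and 12 rose (camera adjusted p = 0.497). They numbered 10 and 8, 8 and 8, 11 and 10, and 13 and 11 with each library left out in turn. obst-A, a chitin-binding protein, fell from 212 ± 8.35 to 21.9 ± 6.63 TPM (log2 fold change -3.25, adjusted p = 0.00067). Cpr47Eb, a cuticle protein, rose from 2.36 ± 0.368 to 22.4 ± 3.72 TPM (log2 fold change 2.79, adjusted p = 0.000621).

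Immune recognition genes moved in both directions. PGRP-SA, a peptidoglycan receptor of the Toll pathway, rose from 6.49 ± 0.516 to 74.8 ± 14.7 TPM (log2 fold change 3.33, SE 0.17, adjusted p = 0.000308). The NF-kappaB factor Dif rose from 4.91 ± 0.912 to 51.6 ± 10.2 TPM (log2 fold change 3.15, SE 0.19, adjusted p = 0.000529). The protease psh rose from 0.515 ± 0.0919 to 9.8 ± 0.601 TPM (log2 fold change 2.83, SE 0.18, adjusted p = 0.000609). GNBP3, a beta-glucan receptor, fell from 231 ± 1.05 to 58.7 ± 8.28 TPM (log2 fold change -1.96, SE 0.13, adjusted p = 0.000725). Of 33 tested Toll and Imd genes 10 rose and 4 fell (camera adjusted p = 0.0808). Those counts were 3 and 1, 3 and 3, 5 and 3, and 9 and 5 with each library left out in turn, against 11 and 3 under median-ratio scaling. Of 11 tested antimicrobial peptide genes 0 passed limma's adjusted threshold (camera adjusted p = 0.214, and 0.00348 without mutant replicate 2), against 1 that was higher without control replicate 2 and 1 without mutant replicate 2. DptA was at 11.7 ± 16.5 TPM in control and 99.8 ± 141 TPM in the mutant (adjusted p = 0.673), with 0 and 23.3 TPM in control replicates 1 and 2 and 199.5 and 0 TPM in mutant replicates 1 and 2. Of 3 tested bomanins and secreted immune peptides 1, Listericin, rose and 1, BaraA1, fell (camera adjusted p = 0.631). The counts were 0 and 0, 1 and 0, 1 and 1, and 1 and 1 with each library left out in turn. Listericin was listed at 0 in both control libraries and at 27.0 and 6.8 TPM in mutant replicates 1 and 2, with adjusted p = 0.0512 without control replicate 1. The call of BaraA1 (log2 fold change -2.26, adjusted p = 0.0195) was lost without control replicate 1 (adjusted p = 0.0728) and without control replicate 2 (adjusted p = 0.112). In the authors' deposited table BaraA1 went the other way, with a log2 fold change of 1.06 and an adjusted p of 0.329. Of 13 tested melanization and thioester genes 4 rose and 2 fell (camera adjusted p = 0.497). These numbers became 1 and 2, 1 and 2, 2 and 2, and 4 and 2 with each library left out in turn. The serpin Spn27A fell from 261 ± 7.86 to 52.7 ± 4.84 TPM (log2 fold change -2.29, adjusted p = 0.000308). The protease MP1 fell from 78.9 ± 9.52 to 11.1 ± 3.64 TPM (log2 fold change -2.76, adjusted p = 0.00137).

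Among markers of muscle, Mlc2, a myosin light chain, rose from 7.06 ± 1.63 to 37.7 ± 6.42 TPM (log2 fold change 2.27, SE 0.20, adjusted p = 0.00156). TpnC73F, a troponin C, rose from 1.82 ± 0.941 to 18.7 ± 0.0354 TPM (log2 fold change 2.84, SE 0.25, adjusted p = 0.00161). Mf, myofilin of the thick filament, rose from 0.37 ± 0.283 to 11.1 ± 1.15 TPM (log2 fold change 3.16, SE 0.22, adjusted p = 0.000823). Of 22 tested differentiated muscle markers 20 rose and 0 fell, 20 and 1 adjusted over the list alone (camera adjusted p = 4.91e-11, and adjusted p = 0.75 with an estimated correlation). Over the 14 muscle markers under 5 TPM in control, the median log2 ratio of mutant replicate 1 to replicate 2 was 0.69, against 0.09 over 510 other such genes that rose. Of 14 tested hemocyte markers 5 rose and 1 fell (camera adjusted p = 0.0314, and adjusted p = 0.962 with an estimated correlation). The counts were 1 and 0 with an adjusted p of 0.117 without control replicate 1, 3 and 1 without control replicate 2, 0 and 0 with 0.0751 without mutant replicate 1, and 1 and 1 without mutant replicate 2. The adjusted p was 0.0717 under median-ratio scaling and 0.062 over genes with a mean of at least 5 TPM. Fat body markers had 1 of 10 higher and 3 lower (camera adjusted p = 0.631). They numbered 0 and 0, 0 and 2, 0 and 2, and 2 and 2 with each library left out in turn, against 2 and 5 adjusted over the list alone and 2 and 2 under median-ratio scaling. Fbp1, a storage protein receptor, fell from 307 ± 172 to 6.45 ± 8.57 TPM (log2 fold change -6.03, adjusted p = 0.0114), a call lost without control replicate 1 (adjusted p = 0.0728) and without control replicate 2 (adjusted p = 0.0501). Tracheal markers had 5 of 14 higher and 5 lower (camera adjusted p = 0.555). Those counts were 3 and 1, 2 and 2, 5 and 3, and 5 and 5 with each library left out in turn, against 5 and 6 adjusted over the list alone. Neuron and glia markers had 5 of 12 higher and 3 lower (camera adjusted p = 0.399). The counts were 3 and 1, 3 and 1, 4 and 1, and 5 and 4 with each library left out in turn, against 5 and 1 under median-ratio scaling. The glial receptor moody rose from 3.82 ± 0.559 to 27.1 ± 1.35 TPM (log2 fold change 2.55, adjusted p = 0.000429). sca, a secreted fibrinogen-related protein of proneural clusters, fell from 31.7 ± 1.83 to 9.82 ± 0.587 TPM (log2 fold change -1.60, adjusted p = 0.000971). Of 3 tested salivary gland markers 1, sage, rose (camera adjusted p = 0.708), a call lost without mutant replicate 1 (adjusted p = 0.133) and without mutant replicate 2 (adjusted p = 0.101). Without control replicate 2 the list had 1 higher and 2 lower, Sgs7 (adjusted p = 0.00481) and Sgs8 (0.00998). The glue gene Sgs7 was at 2245 and 1.67 TPM in control replicates 1 and 2 and at 2.01 and 0 TPM in mutant replicates 1 and 2. The single tested midgut marker, Mal-A5, was at 7.71 ± 2.08 TPM in control and 5.04 ± 0.474 TPM in the mutant (log2 fold change -0.51, adjusted p = 0.0998).

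Of 6 tested sex-biased transcripts 3 fell and 0 rose (4 lower adjusted over the list alone; camera adjusted p = 0.0808, and 0.0497 without control replicate 2). lncRNA:roX2, a dosage compensation RNA made in males, fell from 47.6 ± 3.15 to 8.61 ± 0.0778 TPM (log2 fold change -2.34, SE 0.12, adjusted p = 3e-04). dsx, the sex determination factor, fell from 22.2 ± 1.06 to 5.84 ± 1.05 TPM (log2 fold change -1.77, adjusted p = 0.00154). The Y-linked gene WDY rose from 17.9 ± 6.19 to 1871 ± 546 TPM (log2 fold change 6.64, SE 0.30, adjusted p = 0.000249). WDY belongs to the set of 24 genes at 1000 TPM or more in the mutant, described at the end, whose rise has no settled source. Whether discs of both sexes entered each library is not stated in the labels.

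The largest rises of named genes included that of Arc1, which encodes a capsid-like protein related to retrotransposon Gag and rose from 13.2 ± 2.67 to 10720 ± 216 TPM (log2 fold change 9.58, SE 0.15, adjusted p = 1.36e-05). Snap25, a synaptic SNARE gene, rose from 10.9 ± 1.8 to 6982 ± 1884 TPM (log2 fold change 9.18, SE 0.22, adjusted p = 4.14e-05). Ir40a, an ionotropic receptor, rose from 4.31 ± 1.86 to 1574 ± 120.2 TPM (log2 fold change 8.26, SE 0.25, adjusted p = 7.17e-05). Tg, a transglutaminase, rose from 20.4 ± 2.08 to 5317 ± 91.6 TPM (log2 fold change 7.96, SE 0.11, adjusted p = 1.36e-05). CadN2, a cadherin, rose from 22.8 ± 2.14 to 5603 ± 315 TPM (log2 fold change 7.88, SE 0.12, adjusted p = 1.36e-05). sls, the fly titin of muscle, rose from 159 ± 1.76 to 15300 ± 5.49 TPM (log2 fold change 6.58, SE 0.09, adjusted p = 1.36e-05). Further rises were those of beat-Vb (from 16.5 ± 3.07 to 2793 ± 423 TPM), PNPase (from 34.4 ± 4.3 to 3384 ± 612 TPM) and for, a protein kinase gene (from 56.4 ± 5.64 to 4741 ± 822 TPM), with log2 fold changes of 7.32, 6.58 and 6.36. Over the 24 genes at 1000 TPM or more in the mutant and at least 8-fold higher, the log2 fold change in the authors' deposited table minus the log2 TPM ratio lay at -0.42 relative to other genes (range -2.12 to 1.88). Among genes known by number, CR43086 rose from 0.17 ± 0.0424 to 259 ± 11.6 TPM (log2 fold change 7.79, adjusted p = 1.36e-05), and CG32641 was listed at 0 in both control libraries and at 225 and 371 TPM in mutant replicates 1 and 2 (adjusted p = 7.17e-05). The largest falls of genes with a name after ImpE2, Fbp1, Paip1 and ImpE3 included that of St2, a sulfotransferase gene, which fell from 40.8 ± 8.63 to 0.49 ± 0.368 TPM (log2 fold change -4.82, SE 0.24, adjusted p = 0.000308). Obp99a, an odorant-binding protein gene, fell from 36.3 ± 1.41 to 0.435 ± 0.163 TPM (log2 fold change -4.70, SE 0.16, adjusted p = 9.24e-05). Spn100A, a serpin gene, fell from 55.1 ± 17.4 to 1.3 ± 0.884 TPM (log2 fold change -4.63, SE 0.34, adjusted p = 0.000919). sand, a potassium channel gene, fell from 23.8 ± 7.18 to 0.2 ± 0 TPM (log2 fold change -4.34, adjusted p = 0.000416). CG13053 was listed at 0 in both mutant libraries and at 132 and 183 TPM in control replicates 1 and 2 (adjusted p = 4.43e-05). CG42586 fell from 144 ± 51.1 to 0.35 ± 0.141 TPM (log2 fold change -6.71, adjusted p = 0.000152).

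The authors' deposited table marked 1923 genes as significant, 1437 up and 486 down, each with an absolute log2 fold change of at least 1.001 and an adjusted p of at most 0.0494. Of its marked genes 1486 were among those tested with limma. In the same direction, 968 of 1029 genes up and 441 of 457 genes down in the authors' deposited table were also called here, and 0 were called in the opposite direction.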

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

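Median-ratio scaling, rescaling to a common sum, robust variances and the exclusion of genes with transposon sequence in exons were chosen only after the data were seen. The Paip1 fall kept its direction and its side of the threshold in all settings tried (log2 fold change -4.96 to -5.61). Of the 161 other named genes past the threshold 0 changed sign. Sign changes of named genes that passed neither in the main test nor in the setting were not counted. Leaving out single libraries gave 1013 to 3273 changed genes, 607 to 1089 higher and 406 to 2184 lower, where fewer samples leave less power. With control replicate 1 out, 1000 of the 3852 genes kept their call, and with control replicate 2 out 1071. Under median-ratio scaling 1469 genes were lower and 2812 of the 3852 kept their call; the factors moved the median of all genes from -0.22 to -0.003. With a mean of at least 5 TPM, 955 genes changed at least 2-fold, with fewer genes tested (7186). With camera's estimated correlation 0 lists passed instead of 10. The estimate lay below the preset 0.01 for the damage response (-0.0411) and oxidative stress (-0.0266) lists and above it for all others of the 10. A higher correlation was therefore not what removed the calls of those lists with a lower estimate. With an estimated correlation the test has only the 2 residual degrees of freedom. For the damage response the unadjusted camera p went from 5.55e-10 to 0.0224. That was the lowest of any list in this setting and did not pass adjustment over the 39 lists. The loss of all 10 calls therefore does not decide on single lists. Other list counts were 8 to 12, with 8 by fry. The Wnt, Hh and Dpp (adjusted p = 0.0691) and hemocyte (0.062) calls were lost with a mean of at least 5 TPM, where histones passed (0.0254), and the Wnt, Hh and Dpp call without genes with transposon sequence in exons (0.0781). The alternatives that need counts (DESeq2, its size factors, library totals and legacy dispersions) were not run because the table holds no counts. TPM keeps no depth, so what depth limits cannot be said.

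With the replicate number as a block 4246 genes changed, 1403 higher and 2843 lower, and 3762 of the 3852 kept their call. The number lower went from 1 to 7 of 13 mitochondrially encoded genes, from 3 to 7 of 10 fat body markers, from 5 to 9 of 33 ribosome biogenesis genes and from 13 to 21 of 72 oxidative phosphorylation genes. The number higher went from 4 to 8 of 27 autophagy and lysosome genes, and other list counts stayed within 1.5 times or moved by 1 gene. The correlation of the deviations of same-numbered libraries was 0.065. With 2 pairs this does not show that the numbers pair the libraries.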

Other observations

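The tests of TPM scaling, of the offset from the authors' fold changes, of muscle tissue, of salivary gland tissue and of developmental timing were chosen only after the results were seen. Some genes were listed at 0 in both libraries of one group, which at unknown depth does not show that the transcript was absent. CG34002, the forkhead gene fd102C, CG32641 and lncRNA:CR44117 were listed at 0 in both control libraries and at 20 TPM or more in both mutant libraries. fd102C, on chromosome 4, was at 26.95 and 29.6 TPM in mutant replicates 1 and 2, and CG34002 at 90.8 and 70.1 TPM. CG13053 and the pseudogene CR33255 were listed at 0 in both mutant libraries, with CR33255 at 105 and 96.4 TPM in control replicates 1 and 2. The glue genes of the salivary gland were high in control replicate 1 alone, with Sgs8 at 699 TPM against 0 in control replicate 2, Sgs5 at 351 against 0, Sgs3 at 156 against 0.05 and Sgs4 at 98.8 against 0.

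A set of 24 genes lay at 1000 TPM or more in the mutant and at least 8-fold above control. Together they made up 11.3% and 10.2% of the listed TPM in mutant replicates 1 and 2 against 0.14% and 0.12% in control replicates 1 and 2. Named above were sls, Arc1, Snap25, CadN2, Tg, for, PNPase, Eip63E, beat-Vb, WDY, Ir40a, twin and Ilp8. The others were Myo81F (228 ± 3.63 to 10380 ± 1290 TPM), Lasp, toc, bbg, Nipped-A, mbl, Cul2, rut, CG3726, CG34347 and CG15784. Transposon reads in annotated exons would need many such exons, but 4.2% of the set (1 gene, Nipped-A) had any overlap, against 2.1% of 8581 other tested genes (two-sided Fisher's exact p = 0.4). Median-ratio scaling moves all genes of a library alike and took the median of all tested genes from -0.22 to -0.003. It left the set's median log2 ratio at 6.73 (6.49 before, lowest gene 3.97), so a shift of this size is too small to account for the rises. Reads confined to a short transcript may explain part of the set. The authors' log2 fold change fell short of the log2 TPM ratio with a median offset of -0.42 relative to 4374 other genes. Offsets ran from -2.12 to 1.88. In 15 of the 24 genes the offset lay below -0.06, the 5th percentile of the other genes. The set's median met neither the bound set for a short transcript nor the bound set against it, so it does not decide. The limit for single genes was not part of these bounds. The other genes were all above 20 TPM in both groups, whereas some of the set were lower in control. In these 15 genes the authors' fold change fell short by more than in most other genes. This does not show whether the reads came from a short transcript. The rest of the set lay at or above that limit. Among them Myo81F (offset 1.88) and, to a lesser extent, PNPase and Cul2 lay above the other genes. That is the opposite of what reads confined to a short transcript would give. For the remaining genes a short transcript cannot be told apart from a true rise of full-length transcripts. Transposon insertions absent from the reference and the genetic background of the mutant strain were not tested.

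Of 22 tested muscle markers 20 rose in the mutant, and the most abundant besides sls did not pass the test, with Argk1 at 818 ± 53.6 TPM in control and 478 ± 208 TPM in the mutant and Tm1 at 419 ± 27.2 and 384 ± 104 TPM. A candidate source is larval muscle carried along in unequal amounts: over 14 markers under 5 TPM in control the median log2 ratio of mutant replicate 1 to replicate 2 was 0.69, against 0.09 over 510 other genes that rose. Single markers ran from 0 to 1.11, and muscle genes switched on in the disc to unequal extents would shift this median too, so these explanations cannot be told apart here. The rise of sls needs another source, since Mhc, Mlc1, Mlc2, Act57B, Tm2, up and wupA together reached 181 TPM in the mutant, 1.18% of the 15300 TPM of sls. Of the 22 markers 9 were at 1 TPM or more in both control libraries and 1 stands in another list.

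A set of 49 genes lay at 20 TPM or more in control and at least 8-fold lower in the mutant, ImpE2, ImpE3 and pnr among them. The median log2 ratio of control replicate 1 to replicate 2 over the set was 0.34 (range -1.38 to 1.82). The set took only genes past limma's adjusted threshold. This left out glue genes high in control replicate 1 alone, such as Sgs7 (limma adjusted p = 0.189). A small ratio was therefore favoured by the choice of the set and does not decide on salivary gland tissue. As a hypothesis, mutant discs may have been at an earlier point of the third instar. Of 13 tested genes of the ecdysone response 69.2% fell (9 genes) but 1, ftz-f1, rose, where the bound set for this explanation was 70% with none higher. The share that fell was smaller with any single library left out, most of all without mutant replicate 1, where fewer samples leave less power. The share therefore does not decide on a delay. The bound took ftz-f1 to be induced by ecdysone like the rest, which was not tested, so missing it does not count against a delay. The labels give the stage of both groups as the third instar, and a delay cannot be told apart here from a direct loss of these transcripts.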
